A study of Mus musculus with 27 samples.

How the data were processed

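Whole lungs of 27 mice were profiled by bulk RNA sequencing with polyA selection, with 20 M read pairs (M, mega) of 150 bases planned per sample, per the labels' protocols. Male C57Bl/6 mice of 7 to 8 weeks received 5 oropharyngeal instillations of 10 µg of HDM extract in 50 µl, or PBS, at intervals of 2 to 3 days. At 24 h after the last of these, 100 µl of a suspension of combustion products at 2 mg per ml (200 µg per mouse) or saline was instilled, and lungs were taken 24 h later, all per the labels' protocols. The labels give each library's group and number, and each library is 1 mouse as far as the labels say.

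The deposited tables hold, for 56941 annotated genes, estimated counts and transcripts per M (TPM) of the 27 libraries. STAR (its version is not given in the sources used here), StringTie 2 and the GRCm39 build are named in the submitters' processing notes, and the name of the deposited tables adds GENCODE release M33. The deposited estimated counts are whole numbers whose sums differ between libraries, from 56.3 M to 84.5 M, about 4 times the pairs planned. They were therefore read as estimates and not as 1 count per read pair, and divided by 4 they sum to between 14.1 M and 21.1 M. The size of these estimates makes counting error look smaller than it is for weakly expressed genes, and p-values rest on the spread between mice, which the test estimates from the data. The deposited TPM values were normalized by the authors so that each library sums to between 999899 and 999999, and they carry no depth. All 27 columns of both tables were matched to samples by the number in the label. Genes without a symbol, 310 of them, held 0.060% of the estimated counts. The counting is not stated to use strand, so overlapping and antisense genes cannot be told apart, and paralogs may share reads. Positions are those in the deposited tables. The reference provided was of another build and was not used.

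The estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups with a minimum count of 10 (24629 genes), library sizes were normalized by the trimmed mean of M values, and 1 model with the 4 group means was fitted to all 27 libraries so that all comparisons shared an estimate of the spread. Quasi-likelihood F tests (robust dispersions, two-sided) were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05 and no fold limit. The 5 comparisons were HDM_SAL with PBS_SAL, PBS_CP with PBS_SAL, HDM_CP with HDM_SAL, HDM_CP with PBS_CP and the interaction of both factors. Standard errors were derived from the fold change and its F statistic. Log2 CPM values used a prior count of 2.

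The design, the comparisons, the 46 gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. Genes were named from 3 sources in each comparison: the 10 with the largest positive and the 10 with the largest negative fold change among those called with a mean log2 CPM of at least 1 (leaving out predicted genes and variable immunoglobulin and T cell receptor segments), 20 genes named in advance, and from each list the 4 members with the smallest p, or all called members where there were 5 or fewer. Lists with at least 5 measured members were tested by camera (limma 3.58.1) on voom-weighted log2 CPM with the preset correlation of 0.01, adjusted over the 46 lists of a comparison. Each was tested again with a correlation estimated from the data and by fry, and members were also counted with p-values adjusted over the list alone. No list call in any comparison held with an estimated correlation. fry tests whether a list moves on balance in 1 direction and does not compare it with other genes.

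The alternatives were other scaling factors (median of ratios, upper quartile), DESeq2 1.42.0, limma voom with sample quality weights, no filter and a minimum count of 50, only the groups compared, the 3 runs of library numbers as a block, limma on log2(TPM + 1) and log2(TPM + 0.1) with a mean TPM of at least 0.5 or no filter, a log2 fold limit of 1, and leaving out each library in turn. Added after the data were seen were the values divided by 4, the data without 3 libraries under 60 M, airway marker scores as covariates, and the combustion-product effect averaged over HDM and PBS mice. The labels do not say that the runs of library numbers are batches. Deviations from the group means correlated by 0.010 on average between libraries of 1 run in different groups and by -0.005 between runs, and 12 genes differed between runs. The share of counts in ribosomal RNA genes set the last run (libraries 96 to 105) apart within every group. It was 0.352% to 0.390% against 0.221% to 0.260% in HDM_CP and 0.339% to 0.353% against 0.203% to 0.326% in HDM_SAL. In PBS_CP it was 0.302% to 0.478% against 0.199% to 0.274%, and in PBS_SAL 0.264% to 0.293% against 0.211% to 0.251%. The 3 libraries under 60 M all belong to the last run.

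All pairs of libraries within a group differed beyond counting noise in at least 28.1% of genes, so none was treated as a duplicate. The first and second principal components held 14.1% and 8.37% of the variance of log2 CPM. The tests were tested on simulated data with 24629 genes drawn from the observed means and spreads. For PBS_CP with PBS_SAL, edgeR recovered 86% of 100 genes changed by a log2 fold of 1 and 98% of 100 changed by 2, with 3 false calls (1.60%), against 24 (11.4%) for DESeq2. For HDM_CP with HDM_SAL these were 86%, 98% and 6 false calls (3.16%), against 32 (14.3%) for DESeq2. For HDM_SAL with PBS_SAL they were 88%, 98% and 5 (2.62%), against 20 (9.48%). For the interaction 82% of 400 changed genes were recovered, with 15 false calls. In these simulations the spreads were edgeR's own estimates and genes were drawn independently of each other. Far more genes were changed than were called for combustion products in the real lungs, which eases the Benjamini-Hochberg adjustment. The shares thus do not give the power or the false calls of either tool in the real comparisons. In a simulation of lists for HDM_CP with HDM_SAL, 2 of 2 shifted lists and 0 of 4 unchanged lists were called. Its genes were drawn from their means and spreads only, without correlation between members of a list. It therefore cannot show how often camera with its preset correlation calls unchanged lists in real lungs. When the real HDM libraries were split into other groups, camera with that correlation called between 4 and 26 lists. Epx, 1 of the genes named in advance, was too low in these lungs to be tested.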

Results

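Gene expression was measured by polyA-selected RNA sequencing of whole lungs from 27 male C57Bl/6 mice in 4 groups. Mice received 5 oropharyngeal instillations of house dust mite extract (HDM), an allergen used to induce allergic airway inflammation, or of phosphate-buffered saline (PBS). They were then given 1 instillation of combustion products (CP, from burned paper, plastic and plywood) or saline (SAL), and lungs were collected 24 h later. The groups were PBS_SAL (n = 7), PBS_CP (n = 7), HDM_SAL (n = 6) and HDM_CP (n = 7), and each library is named here by its group and its number in the labels. The deposited estimated counts summed to between 56.3 M and 84.5 M per library (M, mega) over 56941 genes, of which 24629 passed the filter on low counts. Fold changes are given on the log2 scale with their standard error, levels as counts per M (CPM) with the standard deviation, and gene positions on the GRCm39 build. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

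HDM and PBS mice that received saline were compared to describe the lung after repeated allergen exposure without combustion products. The mucus-associated gene Clca1 (chromosome 3, 144709578 to 144738537) rose by 7.51 ± 1.29 in HDM_SAL (adjusted p = 0.0015). Its level was 7.31 ± 2.80 CPM in PBS_SAL (SD, n = 7) and 1332 ± 1031 CPM in HDM_SAL (SD, n = 6), and the lowest HDM_SAL library, at 46.4 CPM, lay above the highest PBS_SAL library, at 11.9 CPM. Muc5ac, a secreted airway mucin, rose by 5.74 ± 0.90 (adjusted p = 0.00071), and Retnla, a product of alternatively activated macrophages and airway epithelium, rose by 5.78 ± 0.70 (adjusted p = 6.4e-05). The chemokine gene Ccl8 (chromosome 11, 82006011 to 82007625) rose by 4.06 ± 0.49 (adjusted p = 6.4e-05), and Il13, which encodes a central type 2 cytokine, rose by 3.82 ± 0.83 (adjusted p = 0.0069). The transcription factor gene Zbtb16, a glucocorticoid-induced gene, fell by 2.16 ± 0.40 on the log2 scale (adjusted p = 0.0025).

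Among the gene lists fixed before the data were examined, goblet cell and mucus genes changed together in HDM_SAL. Of 16 measured members, 12 rose and none fell over all genes tested, 16 rose when adjusted over the list alone, and the median log2 fold change was 4.07. Examples were Muc5b (4.29 ± 0.67), the anion exchanger gene Slc26a4 (4.25 ± 0.50) and the polymeric immunoglobulin receptor gene Pigr (2.86 ± 0.33). The list was called higher by camera (adjusted p = 2.3e-13), with adjusted p = 0.207 with an estimated correlation. Cell cycle genes were higher in 24 of 30 members (27 adjusted over the list alone), among them the mitotic genes Cdk1 (1.75 ± 0.26), Kif20a (1.63 ± 0.25) and Birc5 (1.39 ± 0.23). That list had a camera adjusted p of 4.3e-24 and adjusted p = 0.207 with an estimated correlation. Of 11 alternative macrophage activation genes 5 rose (9 rose and 1 fell adjusted over the list alone), including the chitinase-like genes Chil4 (6.01 ± 0.98) and Chil3 (2.20 ± 0.30), 2 near-identical paralogs whose reads the upstream counting could have shared. Camera gave that list an adjusted p of 6.7e-06, and adjusted p = 0.207 with an estimated correlation. Type 2 cytokine and chemokine genes rose in 5 of 12 members (7 adjusted over the list alone), among them the eosinophil chemokine gene Ccl11 (2.20 ± 0.42) and Ccl17 (2.24 ± 0.44). The camera adjusted p was 0.0013, and adjusted p = 0.469 with an estimated correlation.

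Acute phase and epithelial antimicrobial genes rose in 7 of 16 members (9 adjusted over the list alone), including complement C3 (1.29 ± 0.18) and the siderophore-binding protein gene Lcn2 (1.62 ± 0.34). Camera called the list higher (adjusted p = 4.1e-09, and adjusted p = 0.207 with an estimated correlation). In the list of acute inflammatory cytokines and neutrophil chemokines 4 of 23 genes rose (9 adjusted over the list alone), among them Cxcl5 (3.29 ± 0.58), with a camera adjusted p of 9.1e-05 and adjusted p = 0.469 with an estimated correlation. Ciliated cell genes rose in 4 of 22 members (12 adjusted over the list alone), including the multiciliogenesis genes Mcidas (2.35 ± 0.46) and Deup1 (1.37 ± 0.30), with a camera adjusted p of 9.2e-07 and adjusted p = 0.591 with an estimated correlation. Fibroblast and pericyte genes moved down, with 6 of 18 lower (8 adjusted over the list alone), among them Tcf21, which fell by 0.51 ± 0.12 on the log2 scale. That list had a camera adjusted p of 1.8e-05, and adjusted p = 0.324 with an estimated correlation. Cholesterol synthesis genes rose in 3 of 19 members (12 adjusted over the list alone), including Idi1 (0.44 ± 0.10), with a camera adjusted p of 1.3e-06 and adjusted p = 0.469 with an estimated correlation. Markers of eosinophils did not pass: 0 of 9 were called over all genes (1 adjusted over the list alone) and the camera adjusted p was 0.834. Siglecf, carried by eosinophils and alveolar macrophages, had a log2 fold change of -0.32 ± 0.21 and was called in 0 of 42 other settings. Ear2, an eosinophil ribonuclease gene, was at 0.65 ± 0.20 (adjusted p = 0.052, called in 12 of 42 other settings). Heart muscle genes, listed in advance as markers of other tissue, were called higher by camera (adjusted p = 0.0056, median 0.56, and adjusted p = 0.591 with an estimated correlation), with 0 of 17 members called either over all genes or adjusted over the list alone. Where their transcripts came from was not tested.

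Circadian clock genes differed in 13 of 15 members, with 10 lower and 3 higher in HDM_SAL (11 and 4 adjusted over the list alone). Per1 fell by 1.32 ± 0.30 and Hlf fell by 0.96 ± 0.21 on the log2 scale, while Npas2, which acts in the opposite phase, rose by 1.51 ± 0.29. Of 14 glucocorticoid response genes 6 fell and 1 rose (8 and 2 adjusted over the list alone), among them Zbtb16, above, and Map3k6, which fell by 0.98 ± 0.14 on the log2 scale. Camera gave adjusted p = 3.4e-05 for the clock list and 0.00013 for the glucocorticoid list, and both had adjusted p = 0.207 with an estimated correlation.

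In all, 786 genes rose and 553 fell in HDM_SAL against PBS_SAL, 290 and 16 of them by at least 2-fold. Of the 46 lists 15 were called higher and 6 lower by camera, 0 with an estimated correlation and 7 by fry. With limma on the deposited TPM (transcripts per M), log2(TPM + 1), the split turned to 513 higher and 842 lower, and DESeq2 called 2009 genes against 1339. Leaving out HDM_SAL 99, 54 or 50 or PBS_SAL 80 lowered the number to 602, 696, 699 and 759. HDM_SAL 99, 54 and 50 held 3.09%, 3.86% and 3.26% of their counts in mitochondrial genes, against 2.08% to 2.78% in all other libraries. Whether this bears on the number was not tested. With the ciliated and club cell scores as covariates, chosen after the data were seen, 57 genes were called, although the club cell list holds genes such as Muc5b that HDM itself raised. Those covariates ended the calls of Il13, Zbtb16, Map3k6, Ccl11, Ccl17, Chil4, Lcn2, Cxcl5, Tcf21, Idi1, Mcidas, Deup1 and the clock and cell cycle genes named. Their fold changes stayed in the same direction, for example Il13 4.36 ± 1.09, Ccl17 2.24 ± 0.63 and Tcf21 -0.49 ± 0.15, while Deup1, a ciliated cell gene itself, was at 0.48 ± 0.22. The loss of a call thus does not show that airway content explains it. The call of Cxcl5 was also lost by limma voom with quality weights.

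**Figure D1:**
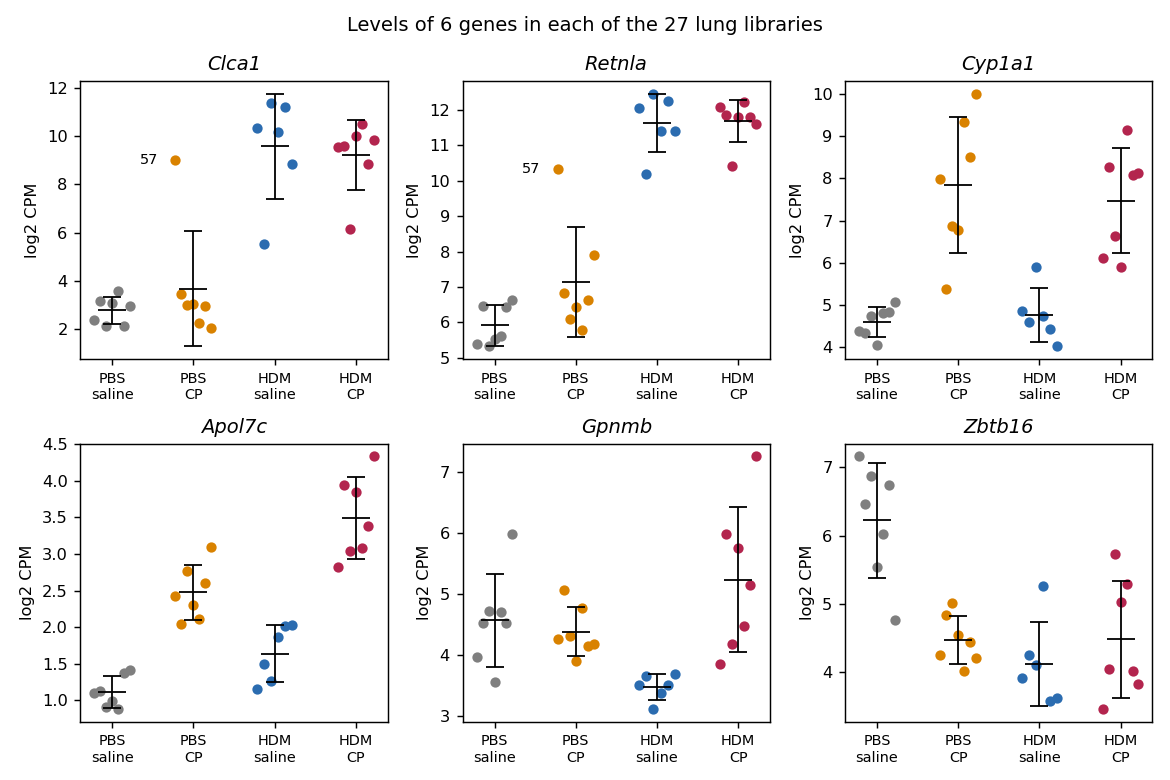
Levels of 6 genes as log2 CPM in each of the 27 libraries, with 1 point per library, a horizontal bar at the group mean and error bars of 1 SD. Clca1 and Retnla were high in the HDM groups and in the library PBS_CP 57, and Apol7c lay between 4.07 and 8.54 CPM in PBS_CP and between 1.81 and 2.64 CPM in PBS_SAL.

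Combustion products were compared with saline in PBS mice to describe the response of lungs without allergen exposure. Cyp1a1 (chromosome 9, 57595211 to 57611107), a cytochrome P450 gene induced through the aryl hydrocarbon receptor, rose by 3.87 ± 0.62 in PBS_CP (adjusted p = 0.028), from 25.0 ± 5.93 CPM in PBS_SAL (SD, n = 7) to 365 ± 356 CPM (SD, n = 7). Apol7c (chromosome 15, 77409052 to 77417516), an apolipoprotein L family gene, rose by 1.41 ± 0.21 (adjusted p = 0.0083), from 2.15 ± 0.33 to 5.71 ± 1.57 CPM, with all 7 PBS_CP libraries above all 7 PBS_SAL libraries. Apol7c has close paralogs in the mouse, and reads could have been shared among them by the upstream counting. Cyp1b1, a related cytochrome gene, had a log2 fold change of 2.49 ± 0.45 that did not pass (adjusted p = 0.099, called in 9 of 42 other settings, DESeq2 and limma voom with quality weights among them), with every PBS_CP library, at 29.5 CPM or more, above every PBS_SAL library, at 13.5 CPM or less. These were the only genes called, 2 higher and 0 lower.

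Of 12 aryl hydrocarbon receptor targets 1 rose over all genes, while 4 rose and 1 fell adjusted over the list alone. Nqo1, a quinone reductase gene, had a log2 fold change of 1.22 ± 0.28 and Aldh3a1, an aldehyde dehydrogenase gene, one of 0.84 ± 0.27, neither called over all genes. The list was called higher by camera (adjusted p = 1.1e-06), with adjusted p = 0.134 with an estimated correlation. Cholesterol synthesis genes had positive fold changes in 19 of 19 members, 0 of them called over all genes and 12 adjusted over the list alone, with values of 0.44 ± 0.10 for Idi1, 0.40 ± 0.11 for Cyp51 and 0.31 ± 0.10 for Fdps. Their camera adjusted p was 5.2e-17, and adjusted p = 0.134 with an estimated correlation. Heat shock genes were called higher by camera (adjusted p = 8.0e-05, and adjusted p = 0.422 with an estimated correlation), with 0 of 11 members called over all genes and 2 adjusted over the list alone. The latter were the paralogs Hspa1a (1.84 ± 0.54) and Hspa1b (1.94 ± 0.55), whose sequences are nearly identical. Clock genes were called lower (camera adjusted p = 8.6e-05, and adjusted p = 0.134 with an estimated correlation), with 0 of 15 members called over all genes, and 9 lower and 4 higher adjusted over the list alone. Ciart, a clock repressor gene, was at -0.54 ± 0.12 and Arntl, which acts in the opposite phase, at 0.86 ± 0.25. Cell cycle genes had positive fold changes in 30 of 30 members with a median of 0.38 and 0 called, over all genes or adjusted over the list alone, and a camera adjusted p of 6.1e-09, and adjusted p = 0.688 with an estimated correlation.

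Acute inflammatory cytokines and neutrophil chemokines had positive fold changes in 20 of 23 members with a median of 0.39, and were called higher by camera (adjusted p = 6.1e-05, and adjusted p = 0.65 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. Ptgs2, which encodes a prostaglandin synthase, was at 0.76 ± 0.23 and Il6 at 1.34 ± 0.47. Acute phase and epithelial antimicrobial genes were called higher as well (median 0.32, camera adjusted p = 0.0015, and adjusted p = 0.688 with an estimated correlation), with 0 of 16 called over all genes or adjusted over the list alone. Neutrophil and goblet cell genes were not called in this comparison (camera adjusted p = 0.378 and 0.107), with 0 members called in either list, also adjusted over the list alone. The fold change of 3.45 ± 1.08 for Clca1 came from the library PBS_CP 57 and was 0.01 ± 0.62 without it, and that of Retnla went from 2.11 ± 0.59 to 0.78 ± 0.36. Over all genes 1343 had an unadjusted p under 0.05, DESeq2 called 32, limma voom with quality weights 15, and the 46 lists gave 11 higher and 2 lower by camera, 0 with an estimated correlation and 0 by fry. The call of Cyp1a1 was lost when any of PBS_SAL 61, 64, 79, 80, 81 or 104 or PBS_CP 76, 101 or 102 was left out, each time leaving 1 gene called, and 5 genes were called without PBS_SAL 105. It was also lost with no filter on low counts, with only the groups compared, with log2(TPM + 1) without a filter, without the 3 libraries with the lowest totals and with airway covariates, and Apol7c was lost only with log2(TPM + 1) without a filter.

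Combustion products were compared with saline in HDM mice to describe the response of lungs with established allergic inflammation. Apol7c rose by 1.92 ± 0.22 (adjusted p = 5.9e-05), from 3.17 ± 0.83 CPM in HDM_SAL (SD, n = 6) to 12.02 ± 4.80 CPM in HDM_CP (SD, n = 7), with all 7 HDM_CP libraries above all 6 HDM_SAL libraries. It was the 1 gene called in this comparison. Cyp1a1 had a log2 fold change of 3.00 ± 0.64 that did not pass (adjusted p = 0.11), with 237 ± 182 CPM in HDM_CP and 29.6 ± 15.6 CPM in HDM_SAL, and Cyp1b1 one of 2.01 ± 0.47 (adjusted p = 0.13). Of 12 aryl hydrocarbon receptor targets 0 were called over all genes and 4 adjusted over the list alone, with a camera adjusted p of 2.2e-05 and adjusted p = 0.116 with an estimated correlation.

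Several lists of inflammatory cells and matrix were called higher in HDM_CP, although none of their members passed over all genes. Of 23 monocyte and recruited macrophage genes 16 were higher adjusted over the list alone, including Gpnmb, a gene of lipid-laden and phagocytic macrophages, at 2.21 ± 0.46 and Cd68 at 0.61 ± 0.18. The camera adjusted p was 6.5e-14, and adjusted p = 0.116 with an estimated correlation. Gpnmb lay at 11.2 ± 1.54 CPM in HDM_SAL (SD, n = 6) and ranged from 14.4 to 154 CPM in HDM_CP. It was at 27.05 ± 17.0 CPM in PBS_SAL and 21.6 ± 6.57 CPM in PBS_CP, so that its fold change reflects in part a low level in HDM_SAL. Neutrophil genes had a median log2 fold change of 1.02 over 21 members, 11 of them higher adjusted over the list alone, among them the collagenase gene Mmp8 (2.00 ± 0.36, called in 7 of 42 other settings) and the lectin receptor gene Clec4d (1.13 ± 0.24). Their camera adjusted p was 8.1e-14, and adjusted p = 0.115 with an estimated correlation. Matrix remodelling genes were higher in 16 of 24 members adjusted over the list alone, with fibronectin Fn1 at 0.62 ± 0.13, Mmp13 at 2.24 ± 0.51 and the protease inhibitor gene Timp1 at 1.26 ± 0.30. The camera adjusted p was 6.5e-14, with adjusted p = 0.115 with an estimated correlation. Dendritic cell genes were higher in 13 of 20 members adjusted over the list alone, including the chemokine gene Ccl22 (0.85 ± 0.19), with a camera adjusted p of 3.0e-09 and adjusted p = 0.148 with an estimated correlation. Acute inflammatory cytokine and chemokine genes were higher in 12 of 23 adjusted over the list alone, including the interleukin-1 receptor antagonist gene Il1rn (1.34 ± 0.29), with a camera adjusted p of 1.3e-10 and adjusted p = 0.116 with an estimated correlation. Regulatory T cell and T helper 2 genes had 5 of 13 higher and 1 lower adjusted over the list alone, with Foxp3 at 0.79 ± 0.26 and Icos at 0.81 ± 0.23, a camera adjusted p of 0.00014 and adjusted p = 0.116 with an estimated correlation.

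Not all immune lists were higher. The interferon gamma response and cytotoxic cell list was called lower (camera adjusted p = 0.017, and adjusted p = 0.521 with an estimated correlation), with 0 of 20 members called over all genes or adjusted over the list alone. Ifng, the interferon gamma gene, was at -1.06 ± 0.36. The call of the list was lost without HDM_CP 45, HDM_SAL 52, HDM_CP 96, HDM_CP 97 or HDM_SAL 99. Mast cell and basophil (camera adjusted p = 0.291), B cell (0.708) and alveolar macrophage genes (0.573) were not called.

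Beside these lists, those of airway, platelet and heart markers were called lower in HDM_CP than in HDM_SAL by camera with its preset correlation only. Ciliated cell genes had a median of -0.32 (camera adjusted p = 3.5e-06, and adjusted p = 0.328 with an estimated correlation), with Tppp3 at -0.36 ± 0.13. Genes of airway xenobiotic metabolism had a median of -0.27 (camera adjusted p = 4.0e-07, and adjusted p = 0.222 with an estimated correlation), with Cyp2f2 at -0.47 ± 0.20. In both lists 0 members were called over all genes or adjusted over the list alone. Platelet genes had 6 of 12 lower adjusted over the list alone, including Gp9 (-0.62 ± 0.19) and Tubb1 (-0.39 ± 0.11), with a camera adjusted p of 5.7e-06 and adjusted p = 0.115 with an estimated correlation. Erythroid genes, the other blood list, were not called (camera adjusted p = 0.882). Heart muscle genes had a median of -0.74 (camera adjusted p = 2.2e-05, and adjusted p = 0.247 with an estimated correlation), with 0 of 17 called over all genes or adjusted over the list alone. Goblet cell genes were not called (Clca1 -0.78 ± 0.99, Muc5ac -0.47 ± 0.73). Ighg1, the immunoglobulin G1 constant region, had a log2 fold change of 5.29 ± 1.07 that did not pass (adjusted p = 0.096). It ranged from 0.97 to 447 CPM among the HDM_CP libraries, against 1.20 to 3.86 CPM in HDM_SAL. Immunoglobulin constant genes are near-identical in part, and their reads could have been shared.

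Over all genes 2388 had an unadjusted p under 0.05, DESeq2 called 192 and limma voom with quality weights 3. Of the 46 lists 23 were called higher and 7 lower by camera, 0 with an estimated correlation and 11 by fry. Leaving out HDM_CP 45, HDM_CP 96, HDM_SAL 99 or HDM_CP 66 raised the number of genes called to 146, 46, 17 and 14, and it was 2 without PBS_CP 59, HDM_SAL 72, PBS_CP 76, PBS_CP 101 or PBS_SAL 105 and 2 with the run of library numbers as a block.

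**Figure D2:**
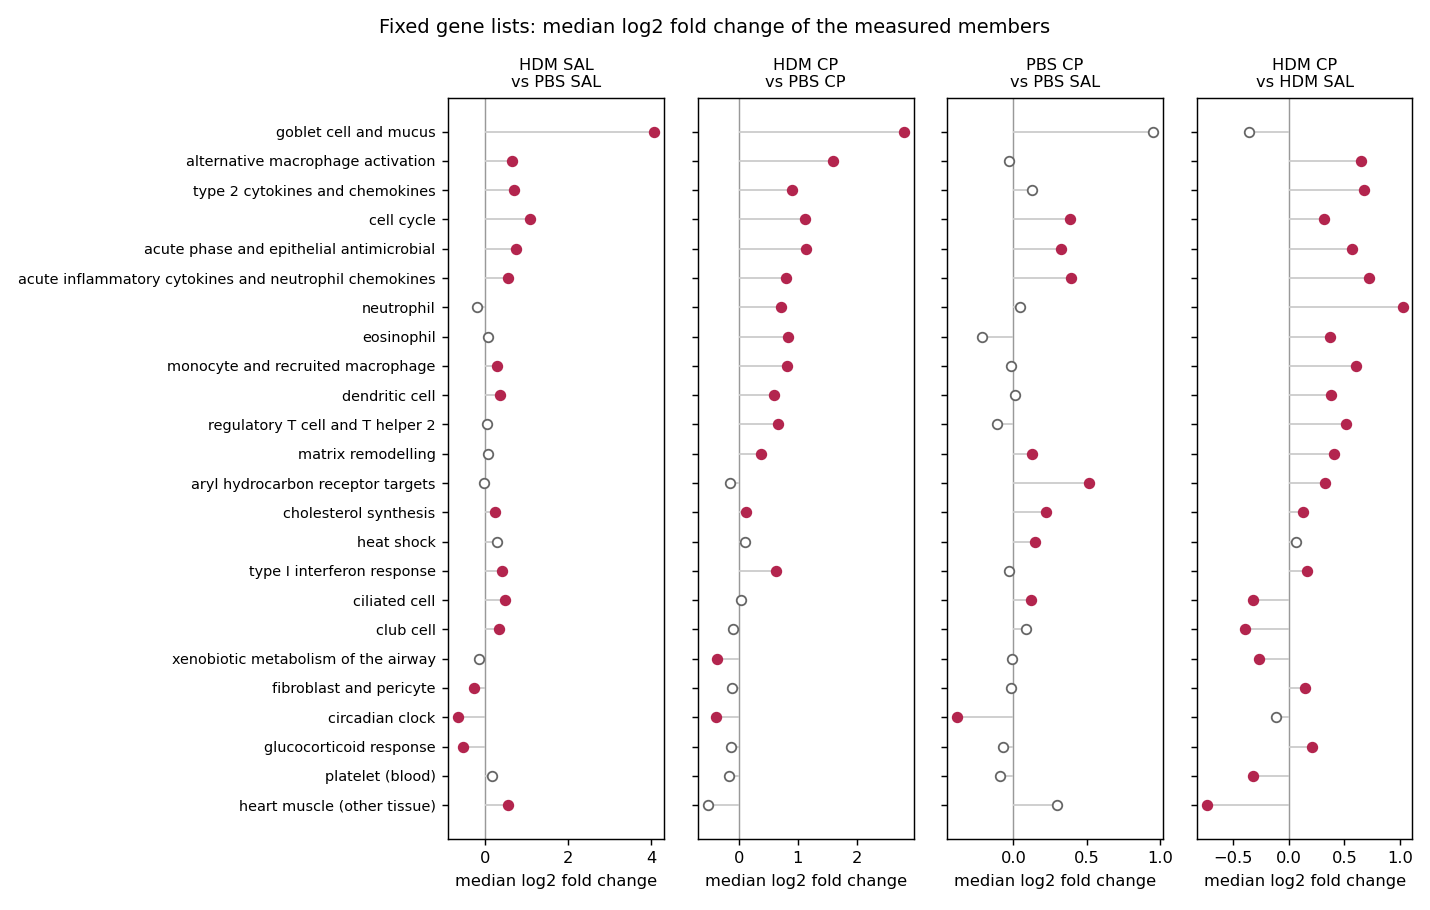
Median log2 fold change of the measured members of 24 of the 46 fixed gene lists in 4 comparisons, with a separate horizontal scale for each comparison. Filled points are lists called by camera with its preset correlation and open points are lists not called, 0 lists were called with an estimated correlation, and the goblet cell median was 4.07 in HDM_SAL against PBS_SAL and 2.80 in HDM_CP against PBS_CP.

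HDM and PBS mice that both received combustion products were compared next. Ccl8 rose by 4.67 ± 0.49 in HDM_CP (adjusted p = 6.9e-06), from 1.82 ± 1.30 CPM in PBS_CP (SD, n = 7) to 46.6 ± 25.3 CPM (SD, n = 7). Arg1, an arginase gene of alternatively activated macrophages, rose by 4.07 ± 0.65 (adjusted p = 0.00036), the eosinophil chemokine gene Ccl24 by 4.08 ± 0.66 (adjusted p = 0.00038) and the macrophage elastase gene Mmp12 by 3.87 ± 0.77 (adjusted p = 0.0026). Ighg1 rose by 7.22 ± 1.13 (adjusted p = 0.00034), and by 5.56 ± 0.84 (adjusted p = 0.00047) without HDM_CP 98, which had 447 CPM. HDM_CP 45, 66 and 96 had 2.11, 1.87 and 0.97 CPM, against a PBS_CP maximum of 1.05 CPM. Coro6 fell by 1.54 ± 0.23 on the log2 scale (adjusted p = 0.00018) and Nqo1 fell by 1.09 ± 0.28 (adjusted p = 0.013).

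Alternative macrophage activation genes rose in 10 of 11 members, also 10 adjusted over the list alone, including Retnla (3.63 ± 0.63) and Chil3 (2.96 ± 0.30). The list had a median of 1.61 and a camera adjusted p of 3.0e-12, and adjusted p = 0.088 with an estimated correlation. Goblet cell genes rose in 12 of 16 (16 adjusted over the list alone), with Slc26a4 at 4.05 ± 0.48 and Muc5ac at 3.16 ± 0.77 (4.90 ± 0.65 without PBS_CP 57), a camera adjusted p of 1.2e-12 and adjusted p = 0.16 with an estimated correlation. Clca1, at 3.28 ± 1.04, did not pass (adjusted p = 0.054, called in 12 of 42 other settings) and was at 6.72 ± 0.77 (adjusted p = 1.8e-05) without the library PBS_CP 57. Cell cycle genes rose in 28 of 30 (29 adjusted over the list alone), including Birc5 (1.31 ± 0.22) and Ube2c (1.30 ± 0.22), with a camera adjusted p of 6.0e-27 and adjusted p = 0.142 with an estimated correlation. Monocyte and recruited macrophage genes rose in 15 of 23 (18 adjusted over the list alone), among them the complement gene C1qa (1.71 ± 0.25), with a camera adjusted p of 2.7e-16 and adjusted p = 0.134 with an estimated correlation. Type I interferon response genes rose in 14 of 25 (20 adjusted over the list alone), including Oas1a (1.16 ± 0.21) and Mx1 (1.19 ± 0.24), with a camera adjusted p of 2.85e-12 and adjusted p = 0.221 with an estimated correlation.

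Eosinophil genes rose in 5 of 9 members (5 adjusted over the list alone), among them the chemokine receptor gene Ccr3 (3.85 ± 0.88) and the granule protein gene Prg2 (3.61 ± 0.92), with a camera adjusted p of 0.0071 and adjusted p = 0.234 with an estimated correlation. The call of Prg2 was lost without HDM_CP 67, those of Ccr3 and Ighg1 with limma voom with quality weights, and those of Ccr3 and Prg2 with log2(TPM + 1) without a filter. Regulatory T cell and T helper 2 genes rose in 4 of 13 (8 adjusted over the list alone), with Foxp3 at 1.26 ± 0.25 and the checkpoint gene Ctla4 at 1.78 ± 0.27, a camera adjusted p of 0.00061 and adjusted p = 0.173 with an estimated correlation. Genes of airway xenobiotic metabolism fell in 8 of 20 members (13 lower and 2 higher adjusted over the list alone), including the sulfotransferase gene Sult1d1, which fell by 1.35 ± 0.32 on the log2 scale, with a camera adjusted p of 2.6e-07 and adjusted p = 0.221 with an estimated correlation. Clock genes had 1 member higher and 1 lower (2 and 5 adjusted over the list alone), with a camera adjusted p of 0.0071 and adjusted p = 0.201 with an estimated correlation, and Nr1d1 fell by 0.73 ± 0.18. Cyp1a1 differed by -0.62 ± 0.55 between HDM_CP and PBS_CP and was not called.

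Here 1378 genes rose and 560 fell, 403 and 22 of them by at least 2-fold, and 20 lists were called higher and 5 lower by camera, 0 with an estimated correlation and 20 by fry. Leaving out HDM_CP 98 lowered the number of genes to 1207. Across genes, the fold changes of HDM against PBS in saline and in combustion-product mice, which share no library, correlated with Pearson's r = 0.445, genes not being independent replicates. Both comparisons called 469 genes higher, against 44.0 if the lists were independent, and 136 lower against 12.6, and 1 gene was called in opposite directions.

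The interaction, the fold change by combustion products in HDM mice minus that in PBS mice, asks whether the response depended on allergen exposure, the question of the study's title. No gene was called by edgeR's quasi-likelihood test, 1571 had an unadjusted p under 0.05, DESeq2 called 6 and limma voom with quality weights 0. Zbtb16 differed by 2.36 ± 0.54 (edgeR adjusted p = 0.69), with 85.0 ± 41.2 CPM in PBS_SAL and 22.8 ± 5.75 CPM in PBS_CP against 19.0 ± 9.86 CPM in HDM_SAL and 26.1 ± 15.9 CPM in HDM_CP. Fkbp5, which like Zbtb16 is induced by glucocorticoids, differed by 0.85 ± 0.19, Ighg1 by 5.38 ± 1.58 and Ighg2b by 5.26 ± 1.40, and these 4 genes were among those called by DESeq2. Gpnmb differed by 2.53 ± 0.61, with its lowest group mean in HDM_SAL, and the neutrophil enzyme gene Padi4 by 0.83 ± 0.21, neither of them called by either tool. Cyp1a1 differed by -0.87 ± 0.80 and Cyp1b1 by -0.48 ± 0.62, so that no difference in these xenobiotic genes between HDM and PBS mice was detectable with this number of mice. The values for Clca1 (-4.22 ± 1.45), Muc5ac (-2.57 ± 1.09) and Retnla (-2.14 ± 0.82) shrank to -0.78 ± 0.85, -0.83 ± 0.81 and -0.81 ± 0.50 without the library PBS_CP 57.

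By camera 13 lists were higher and 7 lower in the interaction, 0 with an estimated correlation and 0 by fry. Monocyte and recruited macrophage genes differed by a median of 0.61 (adjusted p = 5.9e-08, and adjusted p = 0.431 with an estimated correlation), with 0 of 23 called over all genes and 2 adjusted over the list alone. Neutrophil genes differed by a median of 0.92 (adjusted p = 9.0e-07, and adjusted p = 0.431 with an estimated correlation), with 0 and 4 of 21. Ciliated cell genes differed by a median of -0.43 (adjusted p = 5.4e-07, and adjusted p = 0.431 with an estimated correlation), with 0 of 22 called over all genes or adjusted over the list alone. Leaving out HDM_SAL 72 gave 1 gene for the interaction.

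The fold changes by combustion products in PBS and in HDM mice, which share no library, were also set against each other across the 24629 genes. Pearson's r was 0.015 (jackknife SE over libraries 0.087) and Spearman's rho 0.030, and r was 0.139 among genes with a mean log2 CPM of at least 3, genes not being independent replicates. At an unadjusted p under 0.01, 171 genes were higher in PBS mice and 513 in HDM mice, and 20 were higher in both, against 3.56 if the sets were independent. Lower were 152 and 232, with 3 in both against 1.43. The spread of effects beyond their error was 0.055 log2 units in PBS mice and 0.112 in HDM mice. It was taken from a limma voom fit over genes with a mean log2 CPM of at least 3. Variation between mice that many genes share stays in these values, and no standard error was computed for them. Other splits of the HDM libraries gave 387 to 5266 genes with an unadjusted p under 0.05. The higher value in HDM mice therefore does not show a larger effect of combustion products. Apol7c was the 1 gene called in both.

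**Figure D3:**
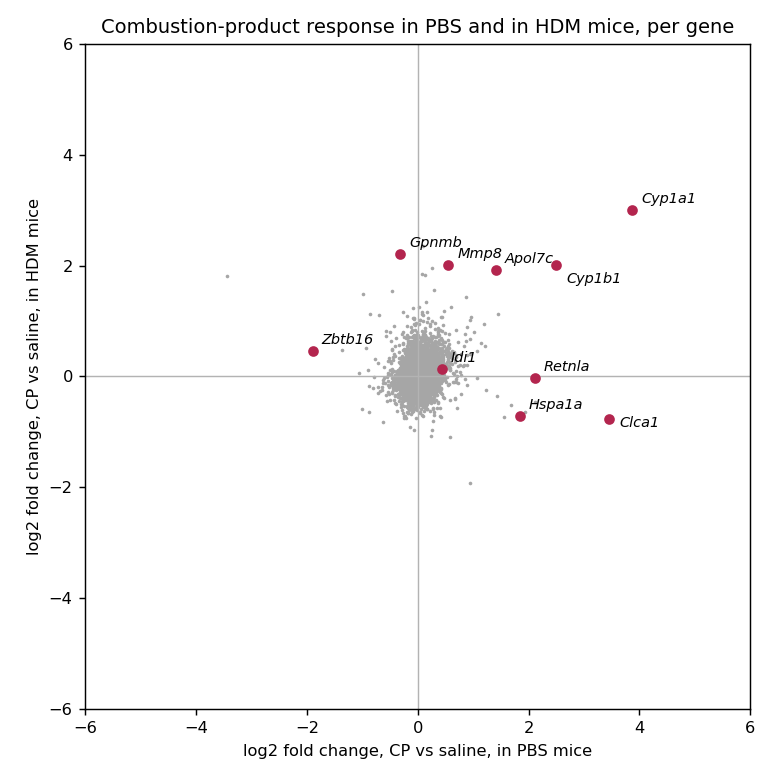
Log2 fold change of combustion products against saline in PBS mice (horizontal) and in HDM mice (vertical), with 1 point for each of 14853 genes with a mean log2 CPM of at least 1 and the named genes in red. Cyp1a1 (3.87 and 3.00), Cyp1b1 (2.49 and 2.01) and Apol7c (1.41 and 1.92) lay to the upper right, while Gpnmb and Mmp8 lay above most genes in HDM mice and Clca1 to the right through the library PBS_CP 57.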

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

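The tests in this part were chosen after the data had been seen, except the 100 splits of the samples per comparison, which were fixed in advance. Dixon's test was applied to 56 measures in each of 4 groups, 224 tests, of which 21 passed, and chance alone flags about 1 in 20 groups.

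The library labelled PBS_CP 57 stood apart from the other PBS_CP libraries in the mean log2 CPM of alternative macrophage activation genes (4.82) and of goblet cell and mucus genes (2.12), and in Clca1 (9.01) and Muc5ac (5.41). In HDM_CP, library 66 stood apart at the low end, with 0.88 for the goblet list, 6.15 for Clca1, 3.73 for Muc5ac and 10.42 for Retnla. On an axis of HDM-responsive genes on which the other PBS_CP libraries average 0 and HDM_CP averages 1, PBS_CP 57 lay at 0.561. A wrong label, an HDM mouse counted as a PBS mouse, cannot be told from this: 0.561 lies just under the lowest HDM_CP library, at 0.577, by less than the SD of that group (0.264). That margin of 1 SD was set after the value had been seen, and without it 0.561 would have counted against a mislabelled HDM_CP mouse. The HDM_SAL libraries ran from 0.407 to 1.24, so on this axis 0.561 lies within the range of HDM mice that received saline. PBS_CP 57 had 253 CPM of Cyp1a1 and 75.8 CPM of Cyp1b1, above the HDM_SAL maxima of 60.2 and 34.8 CPM. Its mean log2 CPM of aryl hydrocarbon receptor targets was 4.72, against 2.85 to 4.16 in HDM_SAL. These values argue against an HDM mouse that received saline, but not against a mislabelled HDM_CP mouse. A swap with an HDM_CP library does not account for it, as no HDM_CP library lay lower than 0.577 and none was near the other PBS_CP libraries (-0.055 to 0.083). RNA carried over from an HDM library could also give the pattern, with a lowest ratio of 0.911 between goblet and other HDM-responsive genes over 13 possible donors, but a search over 13 donors makes this weak support.

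The clock genes set PBS_SAL apart from HDM_SAL and from PBS_CP. Across the 15 clock genes, the difference of HDM_SAL from PBS_SAL correlated at 0.975 with the loadings of the main axis of variation among mice of the same group, and the difference of PBS_CP from PBS_SAL at 0.947, clock genes not being independent of each other. This does not tell causes apart, because both differences share PBS_SAL and the main axis holds 71.7% of the variance within groups: of 1000 differences between random libraries, a share of 0.524 reached 0.7, the bound set for the test, while a share of 0.031 reached 0.975. The first share was taken to void the test, and by the second it would have counted for the hour of harvest. A different hour of harvest in PBS_SAL, a biological shift of the clock by HDM or combustion products and the draw of mice would each move these genes along that axis. The hour of harvest is not given in the sources used here. The low depth of 3 libraries does not account for it, since the clock list kept an adjusted p of 6.0e-05 without them.

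The rise of immune and matrix lists in HDM_CP over HDM_SAL was set against 2 technical explanations. A lower share of airway tissue in the HDM_CP lungs would raise all other tissue alike. Alveolar type 1, endothelial and B cell markers had a median log2 fold change of -0.0392, against 0.61 for the monocyte and recruited macrophage list. Such an even rise thus does not account for the monocyte list. Normalization holds most genes near 0, so these values do not show whether the airway share differed, and the other lists were not set against it. A single library does not carry the rise of the monocyte list, whose camera adjusted p was at most 7.9e-12 when each library was left out, while the call of the type I interferon list was lost without HDM_CP 66 (adjusted p = 0.0527) and that of the T cell list without any of 6 libraries. The size of the monocyte rise varied among mice. The list's mean log2 CPM was 5.57 to 6.39 in HDM_CP 49, 67, 97 and 98 and 5.01 to 5.20 in HDM_CP 45, 66 and 96. HDM_SAL 99 lay at 5.52 and the other HDM_SAL libraries between 4.73 and 4.99. HDM_CP 49, 67, 97 and 98 also had Ighg1 at 26.5 to 447 CPM and lay at 0.989 to 1.25 on the axis of HDM-responsive genes above. HDM_CP 45, 66 and 96 had 0.97 to 2.11 CPM and lay at 0.577 to 0.859. That axis can share genes with the monocyte list. The rise itself rests on camera's preset correlation: with an estimated correlation the monocyte list had an adjusted p of 0.116 and no list was called (smallest 0.115). A hypothesis that these data leave open is that combustion products added monocytes, neutrophils and matrix turnover to the allergic lung, and a test would be cell counts in lavage fluid of the same groups. Mice that differed in their response to HDM could give the same pattern, and this was not tested.

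For the number of genes called, chance is excluded at 1 in 100 splits for HDM_SAL against PBS_SAL (1339, highest other split 614) and HDM_CP against PBS_CP (1938, highest other 7). For PBS_CP against PBS_SAL the count was also reached in 1 of 100 splits, but it is 2 against a highest other of 1. By genes with an unadjusted p under 0.05, 1343 there, other splits had more, up to 2702, so the splits do not settle it. Chance is not excluded for HDM_CP against HDM_SAL (15 of 100 splits with at least as many, real value 1, highest other 1004). For the interaction the splits say nothing about chance, because with a real value of 0 all 100 of 100 have at least as many by construction (highest other 75). For the number of lists, HDM_CP against HDM_SAL lay above every other split (30, highest other 26, 1 of 100 splits). This holds with the preset correlation only, since 0 of the 30 were called with an estimated one, and makes no allowance for the other counts tested. By genes with an unadjusted p under 0.05, 2388 there, other splits had more, up to 5266, so the splits do not settle it. By the number of lists, chance is not excluded for HDM_SAL against PBS_SAL (21, highest other 25, 19 of 100), PBS_CP against PBS_SAL (13, highest other 23, 28 of 100), HDM_CP against PBS_CP (25, highest other 29, 5 of 100) or the interaction (20, highest other 26, 16 of 100). The splits with 1004 and 75 genes point to a structure of the samples, with 8 of 13 and 12 of 27 libraries placed in the other group. Looked at afterwards, the split with 1004 genes parted the HDM libraries along the second principal component: 1 group lay between 17.4 and 54.5, and the other between -57.9 and -8.85 except for HDM_CP 98, at 45.7. In HDM libraries with negative values, the mean log2 CPM of ciliated cell genes was 4.82 to 5.50, except for HDM_SAL 100 at 4.35. In those with positive values it was 4.17 to 4.75. What lies behind that axis was not tested. Both splits were also uneven in number run among the HDM libraries. With 1004 genes, the group set as HDM_CP held 3, 0 and 4 libraries of runs 1, 2 and 3, and that set as HDM_SAL 2, 3 and 1. With 75 genes these were 3, 3 and 1 against 2, 0 and 4. Whether run explains either count was not tested. The split with 614 genes kept 9 of 13 libraries in their real group, so part of its count can come from HDM itself.

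Single libraries stood apart from their group in further measures, given as mean log2 CPM of a list unless stated. HDM_SAL 72 had a total of 83.3 M (mega) and 9.07 for alveolar type 2 cell genes, and HDM_SAL 99 had 5.64 for type I interferon and 5.52 for monocyte and recruited macrophage genes. PBS_SAL 105 had 5.30 for the monocyte list and 6.85 for club cell genes, PBS_SAL 80 had 6.98 for immediate early genes, and PBS_CP 102 had 7.57 for endothelial genes. PBS_CP 76 had 6.16 for oxidative stress genes, 6.87 for airway xenobiotic metabolism and 4.10 for plasma cell genes, HDM_CP 96 had 1.20 for fat genes, and Cyp1b1 in HDM_SAL 100 had a log2 CPM of 0.0105.

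The 20 lists that camera called in the interaction are given with the median of the response to combustion products in HDM mice minus that in PBS mice. The median was 0.46 for alternative macrophage activation, 0.52 for eosinophil, 0.92 for neutrophil, 0.19 for type I interferon, 0.0887 for T cell, 0.67 for regulatory T cell and T helper 2, 0.70 for plasma cell, 0.61 for monocyte, 0.27 for dendritic cell, 0.15 for fibroblast, 0.30 for matrix remodelling, 0.0798 for unfolded protein response and 0.19 for glucocorticoid response genes. It was -0.31 for xenobiotic metabolism, -0.43 for club cell, -0.43 for ciliated cell, -0.14 for cholesterol synthesis, -1.08 for heart muscle, -0.21 for fat and -0.23 for platelet genes. None of these differences was called with an estimated correlation (smallest adjusted p = 0.431). The calls of 6 of them were lost when single libraries were left out: T cell (10 libraries), cholesterol synthesis (9), fat (6), type I interferon (2), unfolded protein response (2) and alternative macrophage activation (1). The run of library numbers as a block ended the calls of T cell (adjusted p = 0.159), cholesterol synthesis (0.363) and fat (0.0768), and leaving out the 3 libraries with the lowest totals those of T cell (0.0970), alternative macrophage activation (0.0678) and eosinophil (0.0508).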

How the results depend on the processing

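The values divided by 4, the data without the 3 libraries with the lowest totals, the airway covariates and the average over HDM and PBS mice were chosen after the data had been seen. For HDM_SAL against PBS_SAL, 1339 genes became 2009 by DESeq2, 764 with log2(TPM + 1) without a filter, 57 with airway covariates, 306 with the fold limit and 602 to 1656 leaving out each library. The 2 genes of PBS_CP against PBS_SAL became 32 by DESeq2, 15 by limma voom with quality weights, 4 with only the groups compared, 4 with log2(TPM + 0.1), 1 without a filter, with TPM without a filter and with airway covariates, and 1 to 5 leaving out each library. The 1 gene of HDM_CP against HDM_SAL became 192 by DESeq2, 3 by voom, 2 with the number run as a block, 3 with log2(TPM + 1), 2 with TPM without a filter, 5 with values divided by 4, 4 without the 3 libraries and 1 to 146 leaving out each library. For HDM_CP against PBS_CP, 1938 genes became 1185 with TPM without a filter, 425 with the fold limit and 1207 to 2600 leaving out each library. The interaction's 0 genes became 6 by DESeq2 and 0 to 1 leaving out each library. For combustion products averaged over HDM and PBS mice, 12 genes became 176 by DESeq2, 33 by voom, 25 with the block, 5 with log2(TPM + 1), 5 with log2(TPM + 0.1), 4 with TPM without a filter, 33 without the 3 libraries, 5 with airway covariates, 6 with the fold limit and 4 to 102 leaving out each library. With an estimated correlation 0 lists were called in each comparison, and by fry 7, 0, 11 and 0 in HDM_SAL against PBS_SAL, PBS_CP against PBS_SAL, HDM_CP against HDM_SAL and the interaction. Leaving out each library gave 20 to 23, 10 to 17, 27 to 30, 22 to 26 and 19 to 22 lists in the 5 comparisons. Pearson's r between the responses to combustion products stayed between -0.016 and 0.050 leaving out each library. Of 67 calls among the genes tracked, 34 held in every setting but the fold limit and 0 turned direction, while 28 of the pairs of gene and comparison not called were called in some setting. No paired analysis was possible because library numbers are not shared between groups.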

Other observations

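The effect of combustion products averaged over HDM and PBS mice, a contrast chosen after the data had been seen, called 10 genes higher and 2 lower. Apol7c rose by 1.66 ± 0.15 (adjusted p = 4.1e-07, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and the aryl hydrocarbon receptor targets Cyp1a1 and Cyp1b1 rose by 3.43 ± 0.45 (adjusted p = 0.00094) and 2.25 ± 0.33 (adjusted p = 0.0034). The dendritic cell chemokine gene Ccl22 rose by 0.77 ± 0.13 (adjusted p = 0.021), Has2, which encodes a hyaluronan synthase, by 1.33 ± 0.24 (adjusted p = 0.029), the metalloprotease gene Adamts9 by 0.46 ± 0.09 (adjusted p = 0.043) and the neutrophil collagenase gene Mmp8 by 1.28 ± 0.25 (adjusted p = 0.046). Lower were Cipc, a clock-interacting repressor gene (-0.15 ± 0.03, adjusted p = 0.044), and Mat2b (-0.11 ± 0.02, adjusted p = 0.044). The value for Mmp8 was 0.55 ± 0.34 in PBS mice and 2.00 ± 0.36 in HDM mice, and that for the transporter gene Slc36a2 (average 0.28 ± 0.05, adjusted p = 0.031) was 0.13 ± 0.07 and 0.42 ± 0.07, so that for both the average rests mainly on HDM mice.

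With the run of library numbers as a block the same contrast called 22 genes higher and 3 lower, adding the cholesterol synthesis gene Idi1 (0.29 ± 0.05, adjusted p = 0.0095), Timp1 (0.94 ± 0.18, adjusted p = 0.040) and the clock gene Ciart (-0.41 ± 0.07, adjusted p = 0.028). Of 100 splits 3 gave at least as many genes as the 12 called without the block, with 242 in the highest other split, and 1 gave at least as many lists as the 28 called with camera's preset correlation, with 25 in the highest other. Both shares are under 0.05, but the splits do not allow for a contrast chosen after the data had been seen, so chance is not excluded. By genes with an unadjusted p under 0.05, 2178 here, other splits had more, up to 4439. The split with 242 genes, which placed 12 of 27 libraries in the other group, points to a structure of the samples. It put all 4 PBS libraries of the last number run into 1 group, and 3 of these (PBS_CP 102, PBS_SAL 104 and PBS_SAL 105) are also the libraries with the lowest totals, so that run and depth cannot be told apart there. The contrast called 25 genes with the run as a block and 33 without those 3 libraries. Without PBS_CP 57 6 genes were called, and without HDM_CP 45 102.

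Among the HDM_CP libraries, Ighg1 was at 43.5, 88.7, 26.5 and 447 CPM in libraries 49, 67, 97 and 98 and at 2.11, 1.87 and 0.97 CPM in libraries 45, 66 and 96. PBS_CP 57, beside its HDM-type genes, had 253 CPM of Cyp1a1, within the range of 41.4 to 1028 CPM of the PBS_CP group.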
